A study of Homo sapiens with 18 samples.

How the data were processed

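Gene expression was measured in 18 cultures, 1 array each: hESC (n = 3), SP (n = 4), Sphere (n = 4), HepaRG D4 (n = 4) and HepaRG D10 (n = 3). Per the labels, 100 ng of RNA from each was labelled with Cy3 and hybridised to Agilent one-colour human arrays, and the groups come from independent experiments. Groups were taken from the labels. The file headers give 8 slides in 3 scan runs. D4 and D10 share a run (D4 array 4 on another day), as do hESC and Sphere, and SP is alone on 1 slide.

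The main values are the intensities of the scanner files as deposited: per the file headers, Feature Extraction 10.7.1.1 or 10.7.3.1 subtracted the background and removed spatial and multiplicative trends within each array, without scaling between arrays. The submitters' notes name version 10.7.3.1 only. The authors' table of log2 values, which the labels describe no further, has column medians from -0.34 to 0.60 and appears centred per probe. Of its columns, all used, 12 matched their own scanner file best and 6 another file of the same group (lowest best correlation 0.999). It thus served only as an alternative and never for single arrays.

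Each probe's processed signals were averaged over spots not marked as outliers, divided by the array's 75th percentile (169 to 741 intensity units across arrays), raised to a floor of 0.0154 and taken to log2. A probe was kept if well above background on every array of at least 1 group, leaving 30904 of 42405. The brightest probe stood for its gene (others can differ), giving 25597 genes tested, 16232 with a symbol. Symbols came from RefSeq accessions (assembly GRCh38.p14); 25460 probes had 1 symbol, 16945 kept their accession, and 1 member of the fixed gene lists could not be resolved. A fold was given as a bound ("at least") where a group was not well above background on any array. A group with at least 1 array well above background counts as measured, with the values of its other arrays at or above the floor, so these changes are not exact. The number of arrays limits the precision. In simulations with their spread but only 200 changed genes, the test found 21 to 32 of 100 changed 2-fold. It found 69 to 83 of 100 changed 4-fold and called 1 to 7 unchanged genes. A list shifted by 0.5 log2 was called in all 5 simulations, and no other. Correlation within lists was not varied.

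Groups were compared with limma 3.58.1 in R 4.3.3 (1 fit of all 18 arrays without covariates, moderated variances, 13 residual and 3.70 prior degrees of freedom) and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05. The 28 gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, which kept 26 of 156 calls; the report names these. Fry, a rotation test of whether a list's genes move one way on balance, compares a list with no other genes. For these list tests 317 missing values in 306 genes were set to the group mean. The comparisons, lists, filters, tests and most alternatives were chosen before the data were examined. The comparison of hESC with Sphere and its overlap with D10 against D4 were added after the scan runs were seen.

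The genes to name were fixed by rule: the 10 largest rises and falls (5 in the comparisons other than Sphere vs D10, SP vs D4 and D10 vs D4) among passing genes whose groups do not overlap and which have a fold measured on both sides, the 3 largest bounds in each direction, up to 4 members of each list with the smallest adjusted p, and ALB, CYP3A4, HNF4A, AFP, KRT19, SOX9, POU5F1, NANOG, ABCG2, LDHA and MKI67 in every comparison. Not all list members that the rule allows are named, and some genes that the rule picks are not reported here.

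The alternatives were quantile normalisation; normexp background correction with an offset of 50 (on median spot signals, since the files hold no mean signals); no filter on dim probes; only probes well above background on all 18 arrays; all probes tested; the mean of a gene's probes; the authors' table; HepaRG-derived groups only; only the groups compared; the replicate number or the slide as a block; robust trended variances; a higher floor; array weights; and leaving out single arrays or both arrays that stood apart (SP 2 and hESC 1). Splits of the samples used the 25291 genes without missing values. Arrays of SP and D10 with the same replicate number deviated together (correlations of 0.14, 0.16 and 0.23), although the labels name no shared origin, so the block is given there beside a call it changes. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the random block with statmod 1.5.0.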

Results

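HepaRG is a human cell line from a liver tumour whose progenitor-like cells can mature into hepatocyte-like and biliary-like cells, and H9 is a human embryonic stem cell line. RNA from 18 cultures was measured on one-colour Agilent whole-genome arrays, so that HepaRG populations with stem-like traits could be set against adherent HepaRG cells and against embryonic stem cells. The groups were adherent HepaRG on day 4 (D4, n = 4) and day 10 (D10, n = 3), the sorted side population, which is the fraction of cells that exports a dye (SP, n = 4), spheres grown in suspension (Sphere, n = 4) and H9 cells on mouse feeder cells (hESC, n = 3). D4 and D10 cells grew in 10% serum with 5 µg/ml insulin and 50 µM hydrocortisone. SP cells were sorted after 5 days in 2% serum with 1 µg/ml insulin and 1 µM hydrocortisone. Sphere cells had the same 5 days and then 5 days in suspension with 20% serum replacement and 4 ng/ml bFGF, and the labels do not say whether insulin or hydrocortisone was present in suspension. Between 56.9% (a D4 array) and 74.9% (a Sphere array) of probes were well above background on an array.

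The groups formed separate clusters, and hESC lay farthest away. The first 3 principal components held 52.1%, 14.7% and 14.3% of the variance. The mean profile of D10 correlated with that of D4 at r = 0.977 across genes, while SP and Sphere correlated with D4 at 0.947 and 0.946 and hESC at 0.802; genes are not independent replicates. D4 and D10 were scanned in 1 run, hESC and Sphere in another, and SP in a run of their own. Only D10 against D4 and hESC against Sphere therefore compare arrays of the same run, and in every other comparison scan run and group cannot be told apart.

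**Figure D1:**
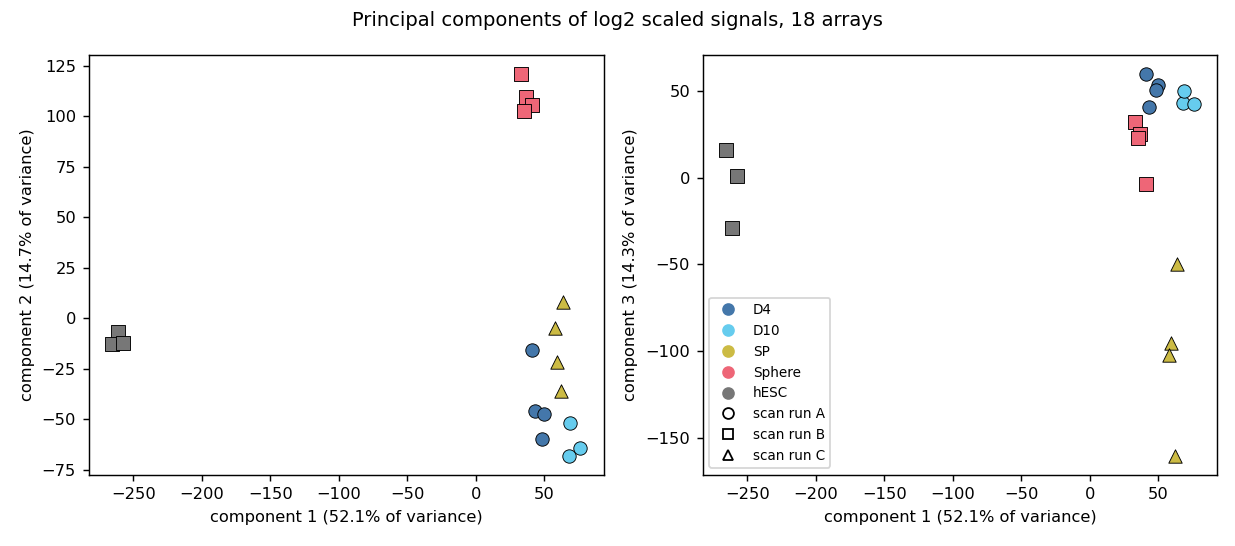
Scores of the 18 arrays on the first principal components of the 25597 tested genes (axes in arbitrary units with the percent of variance), one point per array, coloured by group with the scan run marked. The first component sets the hESC arrays apart.

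Between day 4 and day 10, HepaRG cells gained hepatocyte transcripts. ADH4, an alcohol dehydrogenase of hepatocytes, rose by 6.11 on the log2 scale (69.1-fold, SE 0.523, n = 3 against 4). ALB, the main plasma protein of hepatocytes, rose by 2.10 (4.30-fold, SE 0.293). ADH1A, another alcohol dehydrogenase, rose by 6.08, and CYP8B1, the enzyme that sets the ratio of bile acids, by 6.01 (well above background on 1 of 4 D4 arrays). CNN1, a smooth-muscle calponin of contractile cells, fell by 4.87 (SE 0.441), and POSTN, a matrix protein of activated mesenchymal cells, fell by 4.56. Of 25597 genes tested, 2033 passed in limma's moderated test at an adjusted p under 0.05, 1196 higher and 837 lower on day 10, and 1540 of them differed by at least 2-fold. The count was 1135 without D10 array 2, 1291 without D10 array 3 and 873 with the slide as a block.

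Other large rises were KNG1 (6.17), CFHR2 (5.99), GBA3 (5.96), AFM (5.75), FABP1 (5.69) and SULT2A1 (5.56), which encode plasma proteins, a cytosolic glucosidase, the liver fatty-acid carrier and a steroid sulfotransferase. ADH1B rose at least 91.0-fold, the ketone-body enzyme BDH1 at least 61.3-fold and the urea-cycle enzyme ARG1 at least 33.1-fold, from levels not above background on any D4 array. The other largest falls were AMTN (-4.63), IGFL3 (-4.07), CGB3 (-3.82), PPBP (-3.42), S100A2 (-3.28), SPOCD1 (-3.27), DEFB103B (-3.21) and CCDC80 (-3.13). ODAPH, EVI2B and PSG1 fell at least 15.3-fold, 5.78-fold and 5.77-fold, although EVI2B changed by only -0.81 and did not pass (0.0564) with a convolution-based background correction (normexp). CYP3A4, the main drug-oxidising enzyme of the adult liver, rose by 2.52. HNF4A, the nuclear receptor that maintains hepatocyte identity, was at least 2.93-fold higher, a call that also ended with normexp (0.33, adjusted p 0.578). KRT19, a biliary keratin, passed at -0.87 (adjusted p 0.0358) and lost its call without D4 array 1, 3 or 4 or D10 array 2 or 3 (adjusted p from 0.0561 to 0.188), with the slide as a block (0.239) and in a fit of these groups alone (0.103). AFP, SOX9, POU5F1, ABCG2, LDHA and MKI67 did not pass (adjusted p from 0.175 to 0.947), although SOX9 (0.00837) and MKI67 (0.0185) did with array weights, and NANOG was not above background on any array of either group.

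Of 46 measured genes for secreted hepatocyte proteins, 42 rose (45 adjusted over the list alone), with a median of 2.31 and a camera adjusted p of 5.52e-49. Within the 2 slides that held both days the medians were 2.05 and 2.84. Drug-metabolising enzymes had a median of 1.19 (27 of 53 rose, 30 adjusted over the list alone), led by ADH1C at 5.30. Bile acid genes had a median of 1.57 (14 of 26 rose, 17 adjusted over the list alone), with the bile acid ligase SLC27A5 at 4.95. Among 30 hepatocyte transcription factors, 15 rose (17 adjusted over the list alone; median 0.86), including the nuclear receptors NR0B2 (3.71, with 2 of 4 D4 arrays above background), NR1H4 (3.28) and NR1I2 (2.64). Fatty acid oxidation and ketogenesis (16 of 37 rose, 26 adjusted over the list alone; median 0.84) and amino acid breakdown (21 of 40 rose, 25 adjusted over the list alone; median 1.02) rose too. The tryptophan oxygenase TDO2 rose by 5.02. Extracellular matrix genes fell (13 of 45, 19 adjusted over the list alone; median -0.51), as did epithelial-mesenchymal transition markers (8 of 36, 13 adjusted over the list alone; median -0.72). The basement-membrane collagens COL4A1 and COL4A2 changed by -2.44 and -2.08 and the actin-binding TAGLN by -2.52. These 8 lists kept their calls with an estimated correlation (adjusted p from 0.00137 to 0.0355).

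Cell cycle genes were lower on day 10, with 22 of 57 falling (52 adjusted over the list alone), a median of -1.71 and a camera adjusted p of 1.01e-24, against an adjusted p = 0.144 with an estimated correlation. The mitotic cyclin CCNB1 fell by 2.20 (SE 0.44), a call that ended with the slide as a block (adjusted p 0.074) and in a fit of these groups alone (0.0724). D10 array 1 kept a day 4 level: its mean score over the list was 0.28, inside the D4 range from 0.24 to 0.69, against -2.05 and -1.77 on the other D10 arrays. Without it the median was -2.53 and 48 genes fell; without D10 array 2 or 3 it was -1.23 or -1.35 and 2 genes fell in each case. Between 8 and 15 genes fell without any 1 of the D4 arrays. CDC20, an activator of mitotic exit, fell by 1.77 (adjusted p 0.013), a call that ended without D10 array 2 (0.106) or 3 (0.0906) and with the slide as a block (0.149).

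Gluconeogenesis and glycogen genes rose on day 10 (10 of 21, 11 adjusted over the list alone; median 0.63, camera adjusted p 2.11e-09, adjusted p = 0.0701 with an estimated correlation). The glucose-6-phosphatase gene G6PC1 was at least 8.15-fold higher, and GCKR, the regulator of glucokinase, rose by 3.28. Oxidative phosphorylation genes were slightly higher as a set (1 of 77 rose, 0 adjusted over the list alone; median 0.39, camera adjusted p 1.55e-08, adjusted p = 0.483 with an estimated correlation), as were tricarboxylic acid cycle genes (0 of 31 rose, 0 adjusted over the list alone; median 0.43, camera adjusted p 0.00256, adjusted p = 0.564 with an estimated correlation). Glucocorticoid targets had a median of 0.30 (7 of 25 rose, 10 adjusted over the list alone; camera adjusted p 0.00529, adjusted p = 0.168 with an estimated correlation). Hypoxia genes (4 of 32 fell, 6 adjusted over the list alone; median -0.21, adjusted p = 0.557 with an estimated correlation) lost their call without D4 array 2 (0.0718), D4 array 4 (0.16) or D10 array 1 (0.111) and under quantile normalisation (0.0563). Fibroblast markers (4 of 17 fell, 4 adjusted over the list alone; median -0.25, adjusted p = 0.144 with an estimated correlation) lost theirs without D4 array 2 (0.0528, median -0.08) or 4 (0.0851), and the median was -0.39 without D4 array 3. Median, mean and test differed in sign for the NRF2 and NF-kB lists, neither of which was called.

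**Figure D2:**
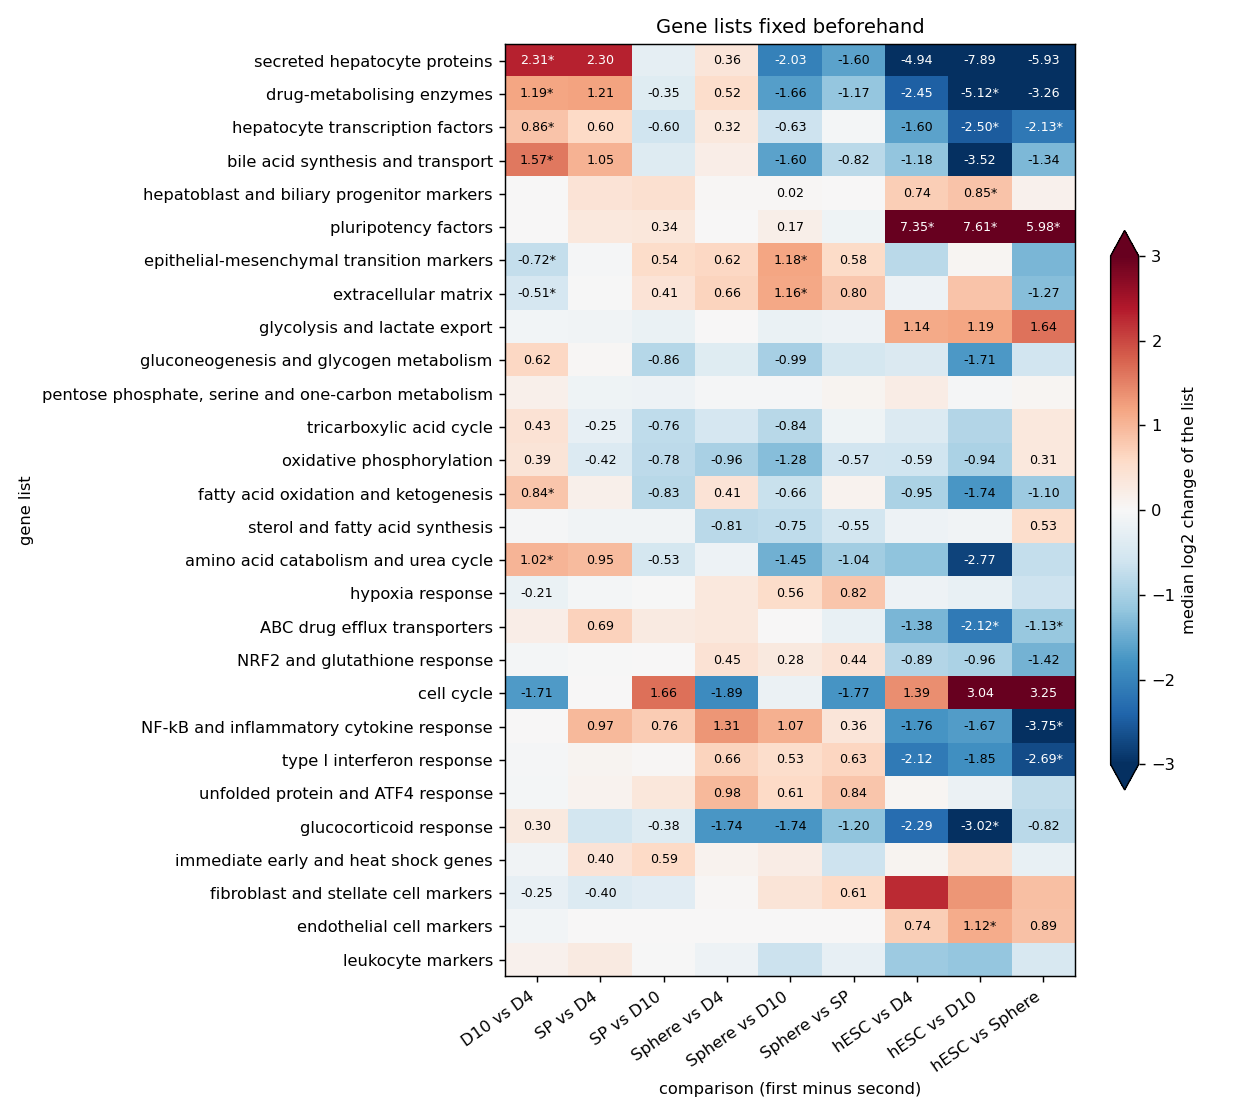
Median log2 change of each of the 28 gene lists (columns, comparisons; rows, lists), with the lists that camera called at an adjusted p under 0.05 marked. Secreted hepatocyte proteins run from 2.31 in D10 against D4 to -7.89 in hESC against D10, and cell cycle genes from 3.25 in hESC against Sphere to -1.89 in Sphere against D4.

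Sphere cells were first compared with adherent cells of day 10. IL6 and IL1B, inflammatory cytokines, rose by 7.25 (152-fold, SE 0.533, n = 4 against 3) and 7.14 (141-fold, SE 0.304). CD36, a fatty-acid and matrix receptor, rose by 8.07 (269-fold), the integrin subunit ITGB3 by 7.73, and COXFA4L3, a mitochondrial respiratory-chain protein induced in inflammation, by 8.91. HAO2, a peroxisomal hydroxyacid oxidase, fell by 7.41 (SE 0.603), and SERPINC1, the plasma inhibitor antithrombin, fell by 6.86 (SE 0.595). CD36, ITGB3 and COXFA4L3 were well above background on 1 of 3 D10 arrays and HAO2 on 2 of 4 Sphere arrays, so their changes are not exact. By limma, 10342 genes passed, 4273 higher and 6069 lower in Sphere, and 6987 differed by at least 2-fold. Scan run and medium differ too and cannot be told apart from the culture form.

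Further large rises were IL4I1 (7.29, with 1 of 3 D10 arrays above background), a secreted amino-acid oxidase, AMTN (6.82), IGFL2 (6.78), IGFBP1 (6.62), a liver protein that binds insulin-like growth factors, and CYP1A1 (6.40), a target of the aryl hydrocarbon receptor. The cytokine IL11, the collagenase MMP1 and the muscle protein CSRP3 were at least 526-fold, 206-fold and 158-fold higher. Further large falls were GBA3 (-6.81), ACSM2B (-6.55), PLAC8 (-6.27), LY6D (-6.26, with 2 of 4 Sphere arrays above background), the tyrosine-breakdown enzyme HPD (-6.20), SAA3P (-6.17), KNG1 (-5.95) and SULT2A1 (-5.86). The B-cell chemokine CXCL13 was at least 811-fold lower, CYP4B1 at least 329-fold and GPM6B at least 150-fold. ALB fell by 1.41 (SE 0.293, adjusted p 0.00107), and CYP3A4 fell by 3.42. HNF4A was lower (-1.77, with 1 of 4 Sphere arrays above background, so not exact). KRT19, AFP, SOX9, NANOG, POU5F1, LDHA, ABCG2 and MKI67 did not pass (adjusted p from 0.0559 to 1), although KRT19 (0.00933) and NANOG (0.0237) did under quantile normalisation. In a fit of these 2 groups alone AFP (0.0348), SOX9 (0.0178), POU5F1 (0.0021), LDHA (0.0105) and NANOG (0.0246) passed, so no absence of change can be read from the main fit. AFP also passed with normexp (0.0488) and among HepaRG-derived groups alone (0.0255). NANOG, above background on all Sphere and no D10 arrays, changed by 4.14 in the authors' table, against 1.37 from the floor here.

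Oxidative phosphorylation genes fell almost as a block in Sphere: 68 of 77 (71 adjusted over the list alone), with a median of -1.28 and a camera adjusted p of 2.43e-18, against adjusted p = 0.233 with an estimated correlation. COX6B1 and COX5B, subunits of cytochrome c oxidase, changed by -1.79 (SE 0.18) and -1.78, and UQCRQ of complex III fell by 1.60. Secreted hepatocyte proteins fell (32 of 46, 32 adjusted over the list alone; median -2.03, camera adjusted p 1.21e-07, adjusted p = 0.293 with an estimated correlation). The iron carrier TF changed by -5.45, APOC3 by -5.47 and the thyroxine carrier TTR by -3.70. Drug-metabolising enzymes fell as a set (31 of 53, 32 adjusted over the list alone; median -1.66, camera adjusted p 1.53e-05, adjusted p = 0.233 with an estimated correlation). MAOA was at -4.70 and EPHX2 at -3.44, while the list members CYP1A1 and CYP1B1 rose, the latter by 4.19. Amino acid breakdown fell (26 of 40, 26 adjusted over the list alone; median -1.45, camera adjusted p 2.84e-07, adjusted p = 0.165 with an estimated correlation). KYNU, a kynureninase of inflamed cells, rose by 4.33. Bile acid genes (15 of 26 fell, 15 adjusted over the list alone), hepatocyte transcription factors (11 of 30 fell, 11 adjusted over the list alone) and gluconeogenesis genes (14 of 21 fell, 14 adjusted over the list alone) were lower, with medians of -1.60, -0.63 and -0.99 and camera adjusted p of 0.00163, 0.00515 and 0.00012. For these 3 lists the adjusted p was 0.165, 0.165 and 0.233 with an estimated correlation; FOXA1, a pioneer factor of liver, fell by 2.39.

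Glucocorticoid targets were lower in Sphere (16 of 25 fell, 16 adjusted over the list alone; median -1.74, camera adjusted p 5.21e-06, adjusted p = 0.0852 with an estimated correlation). FKBP5, ZBTB16 and CIDEC, which respond to glucocorticoid, changed by -4.00 (SE 0.206), -4.16 and -5.04. Sterol and fatty acid synthesis (14 of 35 fell, 15 adjusted over the list alone; median -0.75, camera adjusted p 0.00654), fatty acid oxidation (16 of 37 fell, 16 adjusted over the list alone; median -0.66, camera adjusted p 0.00801) and the tricarboxylic acid cycle (17 of 31 fell, 18 adjusted over the list alone; median -0.84, camera adjusted p 0.00281) were lower too. Each of these 3 had an adjusted p = 0.517 with an estimated correlation. The fatty acid synthase FASN fell by 2.31 and its regulator SREBF1 fell by 1.92.

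Matrix and mesenchymal genes rose in Sphere. Of 45 extracellular matrix genes 27 rose (29 adjusted over the list alone; median 1.16) and of 36 epithelial-mesenchymal transition markers 22 rose (23 adjusted over the list alone; median 1.18), and both calls held with an estimated correlation (0.0071 and 0.00428). The fibrillar collagen COL1A1 rose by 5.26 (SE 0.445), the proteoglycan VCAN by 5.33, POSTN by 6.40, FAP, a protease of activated fibroblasts, by 6.33, and the urokinase receptor PLAUR by 4.59. NF-kB and cytokine genes rose (27 of 46, 30 adjusted over the list alone; median 1.07, camera adjusted p 3.46e-07, adjusted p = 0.149 with an estimated correlation). PTGS2, the inducible prostaglandin synthase, was at least 65.5-fold higher. ATF4 and unfolded protein genes (17 of 35 rose, 19 adjusted over the list alone; median 0.61, camera adjusted p 7.16e-05) and type I interferon genes (16 of 37 rose, 17 adjusted over the list alone; median 0.53, camera adjusted p 0.000728) each had an adjusted p = 0.165 with an estimated correlation. The cystine transporter SLC7A11 rose by 5.19 and the asparagine synthase ASNS by 2.36. Hypoxia genes rose (13 of 32, 15 adjusted over the list alone; median 0.56, camera adjusted p 0.00415, adjusted p = 0.333 with an estimated correlation). The lipase inhibitor ANGPTL4 rose by 5.72 and the hexokinase HK2 by 2.29.

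Stem-cell lists had small medians in Sphere against D10, with members going both ways. Members at the floor in both groups count as unchanged and pull a median to 0. Pluripotency factors passed narrowly (9 of 38 rose and 3 fell, 9 rising adjusted over the list alone; median 0.17, camera adjusted p 0.0469, adjusted p = 0.28 with an estimated correlation). That call ended without Sphere array 3 (0.0724, median 0.00), D10 array 1 (0.0577) or D10 array 3 (0.0559, median 0.06) and under quantile normalisation (0.0624). LEFTY1, a signalling inhibitor expressed in stem cells, was at least 77.1-fold higher, and KLF4 rose by 2.92. Hepatoblast and biliary markers were called (12 of 36 rose and 8 fell, 14 and 8 adjusted over the list alone; median 0.02, camera adjusted p 0.0248, adjusted p = 0.12 with an estimated correlation). The oncofetal RNA-binding protein IGF2BP3 rose by 4.68 and the fetal RNA H19 fell by 5.56 (2 of 4 Sphere arrays above background). That median lay between 0.00 and 0.06 without Sphere array 1, 3 or 4 or any D10 array. The NRF2 list (9 of 32 rose, 9 adjusted over the list alone; median 0.28, camera adjusted p 0.0469, adjusted p = 0.545 with an estimated correlation) lost its call without Sphere array 1 (0.0683) or 2 (0.067) or D10 array 2 (0.056) or 3 (0.0501). No call was made for cell cycle genes (1 of 57 rose and 1 fell, 1 and 0 adjusted over the list alone; camera adjusted p 0.933), but without D10 array 1 they were higher in Sphere (median 0.54, 10 rose, adjusted p 0.000251). The glycolysis, cell cycle and endothelial lists had a median, mean and test that differed in sign.

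**Figure D3:**
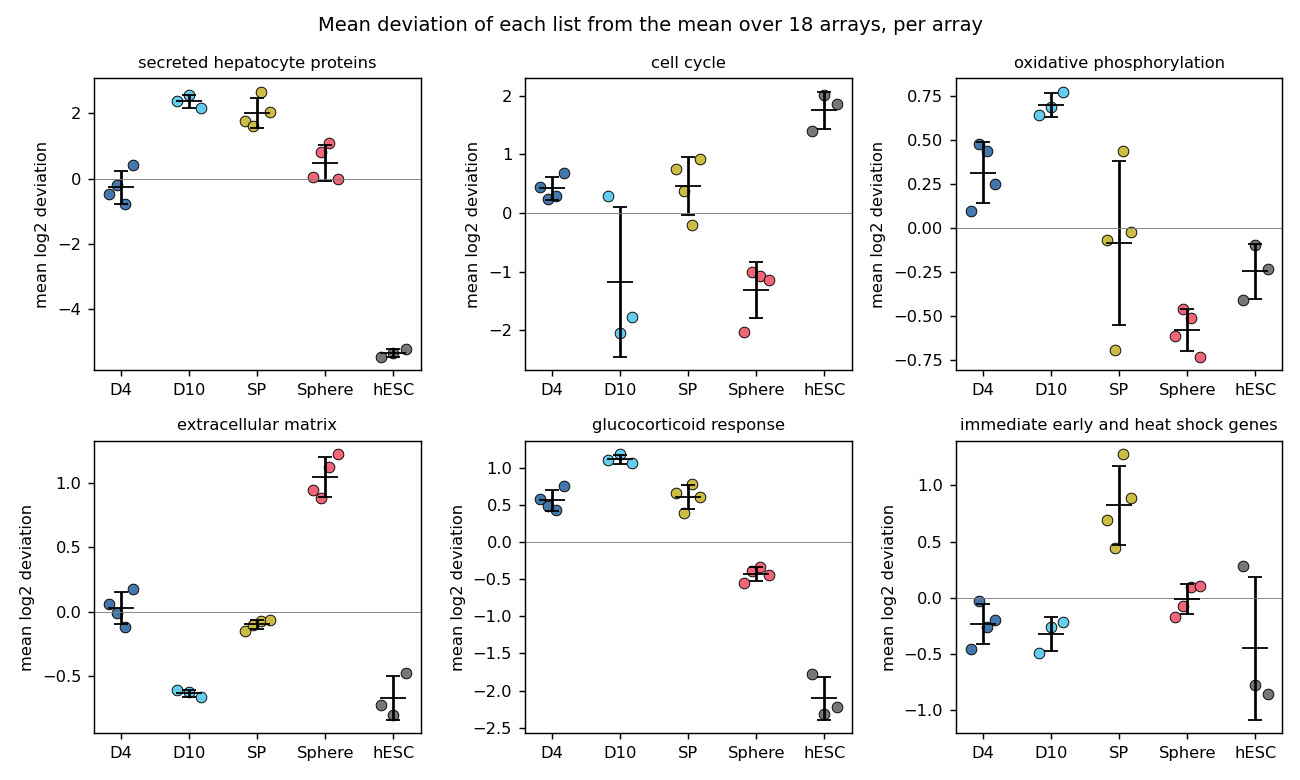
Mean log2 level of selected gene lists on each of the 18 arrays (vertical axis, relative to the mean of all arrays), one point per array and a bar at each group mean. The cell cycle score of D10 array 1 is 0.28 against -2.05 and -1.77 on the other D10 arrays, and the oxidative phosphorylation scores of Sphere lie between -0.73 and -0.46.

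Sphere cells were also compared with day 4 cells. CD36 rose by 8.10 (SE 0.325, n = 4 against 4), CYP1A1 by 7.59, the pantetheinase VNN1 by 7.32, ANXA10 by 7.17 and IL1B by 6.89. The largest falls were those of H19 (-7.07, SE 0.317, with 2 of 4 Sphere arrays above background), PLAC8 (-6.66), EVA1C (-6.07), STAC2 (-5.92) and TNS4 (-5.42). MMP1, the anion transporter SLC22A11 and KRT23 were at least 244-fold, 132-fold and 67.7-fold higher, and the basal keratins KRT6A and KRT5 and GPM6B were at least 172-fold, 84.5-fold and 130-fold lower. In limma's test 10096 genes passed, 4313 higher and 5783 lower, and 6007 differed by at least 2-fold. Scan run, medium and culture time (10 days for Sphere, 4 for D4) cannot be told apart from the sphere culture.

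Cell cycle genes were lower in Sphere than on day 4 (48 of 57 fell, 50 adjusted over the list alone; median -1.89, camera adjusted p 4.94e-10, adjusted p = 0.488 with an estimated correlation). The mitotic genes HMMR and CDC20 changed by -2.97 and -2.32. Lower levels were found for oxidative phosphorylation genes (59 of 77, 64 adjusted over the list alone; median -0.96, camera adjusted p 5.07e-13, adjusted p = 0.445 with an estimated correlation), and none rose. NF-kB genes rose (30 of 46, 32 adjusted over the list alone; median 1.31, camera adjusted p 2.04e-09, adjusted p = 0.106 with an estimated correlation), as did extracellular matrix genes (21 of 45, 22 adjusted over the list alone; median 0.66, camera adjusted p 4.29e-05, adjusted p = 0.106 with an estimated correlation). Glucocorticoid targets fell (16 of 25, 17 adjusted over the list alone; median -1.74, camera adjusted p 0.000197, adjusted p = 0.157 with an estimated correlation), FKBP5 with -3.69. Secreted hepatocyte proteins were higher as a set (19 of 46 rose, 20 adjusted over the list alone; median 0.37, camera adjusted p 0.00289, adjusted p = 0.578 with an estimated correlation), and SERPIND1 rose by 5.38 (2 of 4 D4 arrays above background). That median was 0.63, 0.57, 0.21 and 0.76 without Sphere array 1, Sphere array 4, D4 array 3 and D4 array 4.

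Of the other lists, ATF4 and unfolded protein, interferon, epithelial-mesenchymal transition, drug-metabolising, fatty acid oxidation, NRF2 and hepatocyte transcription factor genes were called higher and sterol and fatty acid synthesis lower, and none of these calls held with an estimated correlation (adjusted p from 0.106 to 0.578). The call ended for transcription factors without Sphere array 2 (0.052) or D4 array 3 (0.0574), for fatty acid oxidation without Sphere array 2 (0.052) or D4 array 1 (0.0718), and for NRF2 genes without Sphere array 1 (0.0618), Sphere array 2 (0.0543) or D4 array 1 (0.0682). SOX9, a biliary progenitor factor, rose by 1.46 (adjusted p 0.00284). AFP (0.87), MKI67 (-1.21), CYP3A4 (-0.90) and NANOG (at least 2.10-fold higher) passed narrowly (adjusted p from 0.0367 to 0.0442). AFP lost its call without Sphere array 1, 2 or 3 or D4 array 1, 3 or 4 (adjusted p up to 0.115), and CYP3A4 without Sphere array 1 or 2 or D4 array 1, 2 or 3 (up to 0.138). MKI67 lost its call without Sphere array 1, 3 or 4 or D4 array 1, 2 or 3 (up to 0.136), and NANOG without Sphere array 1, 2 or 3 or any D4 array (up to 0.148). The NANOG call also ended with normexp (0.04, adjusted p 0.908) and at a higher floor (0.27, adjusted p 0.645), and MKI67 did not pass under quantile normalisation (0.0558). ALB (0.0525), LDHA, POU5F1, KRT19, HNF4A and ABCG2 did not pass. However, ALB did under quantile normalisation (0.96, adjusted p 0.0131) and with normexp (0.0174), and LDHA (0.0091) and POU5F1 (0.0209) did in a fit of these groups alone. Median, mean and test differed in sign for the pluripotency, glycolysis, one-carbon, endothelial and leukocyte lists.

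SP cells were compared with day 4 cells. FOSB, a rapidly induced transcription factor, rose by 7.73 (213-fold, SE 0.817, n = 4 against 4), CYP1A1 by 6.60 (SE 0.4) and IGFBP1 by 6.49 (SE 0.389). The albumin gene ALB rose by 2.15 (SE 0.271). HSPB3, a small heat shock protein, fell by 4.51 (SE 0.277). In limma's test 10087 genes passed, 5619 higher and 4468 lower, and 6079 differed by at least 2-fold; under quantile normalisation the split was 4381 higher and 5555 lower. SP arrays had a run and software version of their own, which with grid, sorting and medium cannot be told apart from the population.

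Other large rises were AFM (5.55), HABP2 (5.53, with 1 of 4 D4 arrays above background), GNRH1 (4.80), the stress-induced MAFF (4.78) and the liver RNA HULC (4.72). KRT23, NEB and the growth factor CSF2 were at least 21.3-fold, 18.7-fold and 13.7-fold higher. Other large falls were those of DDIT4 (-4.21), an inhibitor of growth signalling, COL8A2 (-3.98), CRIM1 (-3.88), PLAC8 (-3.83), CEMIP (-3.69), CADM3 (-3.63), GPM6B (-3.61) and IGFL3 (-3.60), with CRIM1 above background on 1 of 4 SP arrays and CEMIP and CADM3 on 2. FAP, RANBP3L and EPYC were at least 25.1-fold, 19.4-fold and 18.2-fold lower. SOX9 rose by 2.04, POU5F1, which encodes a core pluripotency factor, by 1.60 (adjusted p 0.00213) and the proliferation marker MKI67 by 2.22, while NANOG, well above background on 2 of 4 SP arrays, was at least 3.21-fold higher (adjusted p 0.0062). At a higher floor NANOG changed by 0.95 and did not pass (0.0639), nor did it in a fit of these groups alone (0.0575). CYP3A4 rose by 1.83, and HNF4A, well above background on 3 of 4 SP arrays, was at least 2.47-fold higher. With normexp HNF4A changed by 0.47 and did not pass (0.0649), nor at the higher floor (0.30, adjusted p 0.082). ABCG2, the transporter most often tied to the side population, rose by 0.85 (SE 0.32, adjusted p 0.043). That call ended without SP array 1 (0.106), 2 (0.107) or 4 (0.0523), D4 array 1 (0.0907), 2 (0.0718) or 4 (0.0998), and with normexp (0.133) or quantile normalisation, where the change was 0.25. AFP, KRT19 and LDHA did not pass (adjusted p from 0.453 to 0.976).

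Secreted hepatocyte proteins were higher in SP (41 of 46 rose, 42 adjusted over the list alone; median 2.30, camera adjusted p 1.56e-16, adjusted p = 0.237 with an estimated correlation). ITIH4, VTN and SERPINA1, plasma proteins made by the liver, rose by 3.71, 3.09 and 2.64. Drug-metabolising enzymes rose (33 of 53, 33 adjusted over the list alone; median 1.21, camera adjusted p 1.03e-07, adjusted p = 0.237 with an estimated correlation), with UGT2B10 at 3.12. Bile acid genes (14 of 26 rose, 16 adjusted over the list alone; median 1.05, camera adjusted p 3.5e-05, adjusted p = 0.237 with an estimated correlation) and amino acid breakdown (23 of 40 rose, 24 adjusted over the list alone; median 0.96, camera adjusted p 0.000245, adjusted p = 0.411 with an estimated correlation) were higher. CYP8B1 rose by 4.08 (1 of 4 D4 arrays above background) and the urea-cycle entry enzyme CPS1 by 2.66. NF-kB and cytokine genes rose (25 of 46, 26 adjusted over the list alone; median 0.97, camera adjusted p 3.18e-05, adjusted p = 0.237 with an estimated correlation). The chemokine CCL20 rose by 4.54 and TNFAIP3, a brake on NF-kB, by 3.56 (SE 0.197).

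ABC drug efflux transporters were higher in SP (12 of 22 rose, 12 adjusted over the list alone; median 0.69, camera adjusted p 0.0334, adjusted p = 0.237 with an estimated correlation), a call that ended without SP array 3 (0.122) or D4 array 3 (0.0731). The conjugate exporter ABCC2 rose by 1.96 (SE 0.291) and the sterol exporter ABCG1 by 1.30. Immediate early and heat shock genes rose (13 of 36, 14 adjusted over the list alone; median 0.40, camera adjusted p 0.0241, adjusted p = 0.627 with an estimated correlation), and the call ended without SP array 3 (0.16). ATF3 rose by 3.97, KLF4 by 3.63 and NR4A2 by 2.86. Oxidative phosphorylation genes were lower (25 of 77 fell, 23 adjusted over the list alone; median -0.42, camera adjusted p 6.27e-05, adjusted p = 0.877 with an estimated correlation). Their median was -0.21 without SP array 2, and the adjusted p was 0.0644 under quantile normalisation. Hepatocyte transcription factors (13 of 30 rose, 13 adjusted over the list alone; median 0.60, adjusted p = 0.395 with an estimated correlation) lost their call without SP array 3 (0.128) or D4 array 3 (0.0545). Tricarboxylic acid cycle genes (8 of 31 fell, 8 adjusted over the list alone; median -0.25, adjusted p = 0.907 with an estimated correlation) lost theirs without SP array 1 (0.0668), SP array 2 (0.412) or D4 array 4 (0.197), and also under quantile normalisation (0.456); the median was -0.51 without SP array 3. Fibroblast markers (6 of 17 fell, 6 adjusted over the list alone; median -0.40, adjusted p = 0.237 with an estimated correlation) lost their call without SP array 3 (0.0589) or D4 array 4 (0.0613), and had medians of -0.24 without SP array 2 and without D4 array 3. DCN and LUM, matrix proteoglycans on that list, changed by -3.24 and -2.72. No call was made for cell cycle genes (1 of 57 rose and 2 fell, 1 and 0 adjusted over the list alone; camera adjusted p 0.818). Signs differed between median, mean and test for the epithelial-mesenchymal, one-carbon, cell cycle, interferon, unfolded protein, glucocorticoid and leukocyte lists.

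**Figure D4:**
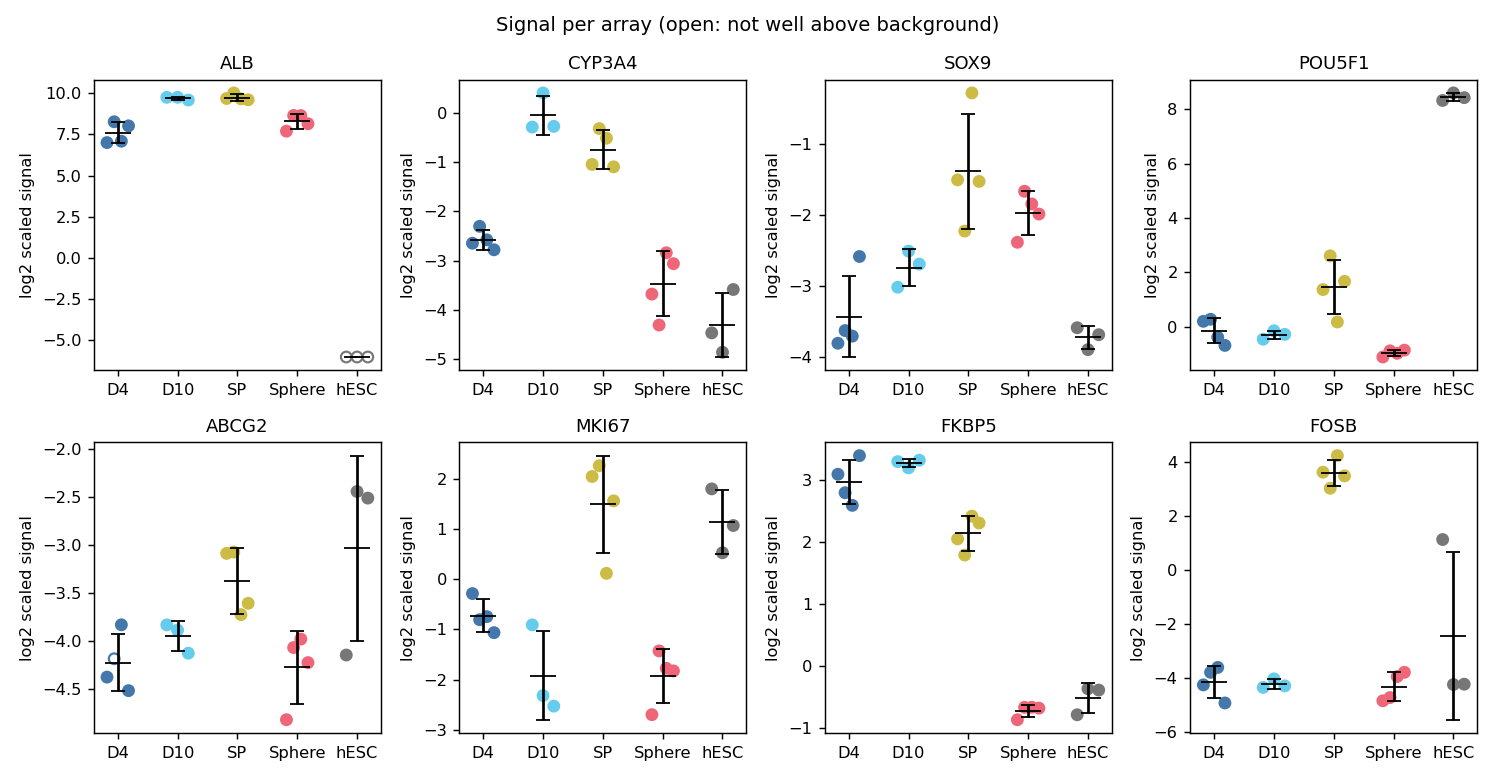
Log2 level of selected genes relative to the 75th percentile of each array (vertical axis), one point per array and a bar with the standard deviation at each group mean. ALB is higher in D10 and SP than in D4 and lower in hESC than in every HepaRG-derived group.

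SP cells were next compared with day 10 cells. FOSB rose by 7.81 (SE 0.883, n = 4 against 3), IGFBP1 by 6.46, CYP1A1 by 5.41, PDE4D, which degrades cyclic AMP, by 4.73 and MAFF by 4.71. CYP4B1 (-5.70, SE 0.328), SAA3P (-4.97), LY6D (-4.67), CXCL13 (-4.49) and RIPOR2 (-4.29, other probe -1.45, 2 of 4 SP arrays above background) fell most. ALB did not differ beyond the error (0.04, SE 0.293). SERPINB2, ANKRD30BP2 and KRT23 were at least 30.2-fold, 24.6-fold and 20.5-fold higher, and EPYC, SHISAL2B and ABHD1 at least 22.8-fold, 15.5-fold and 14.6-fold lower. The limma test passed 9808 genes, 5233 higher and 4575 lower, and 6453 differed by at least 2-fold; under quantile normalisation the split was 4479 and 5614. Scan run, medium, sorting and culture time (5 days against 10) cannot be told apart.

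Cell cycle genes were higher in SP than on day 10 (39 of 57 rose, 42 adjusted over the list alone; median 1.66, camera adjusted p 3.21e-09, adjusted p = 0.441 with an estimated correlation). Without D10 array 1 the median was 2.54 and 52 rose, and without D10 array 2 or 3 it was 1.19 or 1.37 and 20 or 21 rose. MKI67 rose by 3.42 and MCM2, part of the replicative helicase, by 2.13. Oxidative phosphorylation genes fell (50 of 77, 55 adjusted over the list alone; median -0.78, camera adjusted p 6.29e-12, adjusted p = 0.441 with an estimated correlation), and NDUFB5 of complex I fell by 1.69. Fatty acid oxidation (18 of 37 fell, 22 adjusted over the list alone; median -0.83), gluconeogenesis (13 of 21 fell, 15 adjusted over the list alone; median -0.87), the tricarboxylic acid cycle (14 of 31 fell, 14 adjusted over the list alone; median -0.76, or -0.47 without SP array 2), amino acid breakdown (16 of 40 fell, 17 adjusted over the list alone; median -0.53) and hepatocyte transcription factors (13 of 30 fell, 13 adjusted over the list alone; median -0.60) were lower. For these 5 lists the adjusted p was 0.441 or 0.462 with an estimated correlation.

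NF-kB (20 of 46 rose, 22 adjusted over the list alone; median 0.76), immediate early (11 of 36 rose, 11 adjusted over the list alone; median 0.60), epithelial-mesenchymal transition (15 of 36 rose, 16 adjusted over the list alone; median 0.54) and extracellular matrix genes (18 of 45 rose, 20 adjusted over the list alone; median 0.41) were higher in SP than on day 10, with an adjusted p of 0.331 or 0.441 with an estimated correlation. Drug-metabolising enzymes were lower (15 of 53 fell, 15 adjusted over the list alone; median -0.35, adjusted p = 0.649 with an estimated correlation), and that call ended without SP array 1 (0.0824), SP array 2 (0.107) or D10 array 1 (0.0791). Their median was -0.14 without SP array 2 and -0.53 without SP array 3. Pluripotency factors (14 of 38 rose, 14 adjusted over the list alone; median 0.34, adjusted p = 0.441 with an estimated correlation) lost their call without SP array 2 (0.0728, median 0.21) or D10 array 1 (0.0791), and glucocorticoid targets (10 of 25 fell, 10 adjusted over the list alone; median -0.38, adjusted p = 0.441 with an estimated correlation) without SP array 2 (0.0754). Under quantile normalisation the calls ended for drug-metabolising enzymes (0.229), pluripotency factors (0.0799), amino acid breakdown (0.0933) and glucocorticoid targets (0.142). No call was made for secreted hepatocyte proteins (0 of 46 rose and 8 fell; median -0.28, camera adjusted p 0.0704) except with the replicate number as a block (0.048). POU5F1 rose by 1.75 and SOX9 by 1.35, and SOX9 did not pass under quantile normalisation (0.0601) or in a fit of these groups alone (0.0568). NANOG, well above background on 2 of 4 SP arrays, was at least 3.21-fold higher, but changed by 0.95 at a higher floor, where it did not pass (0.0851), nor did it in a fit of these groups alone (0.0947). KRT19 rose by 0.79, a call that ended without D10 array 2 (0.68, adjusted p 0.0809) or 3 (0.66, adjusted p 0.0869). CYP3A4, HNF4A, AFP, ABCG2 and LDHA did not pass, although HNF4A did under quantile normalisation (-0.89, adjusted p 0.00169) and CYP3A4 with normexp (-0.57, adjusted p 0.0435). In the hypoxia and NRF2 lists, median, mean and test differed in sign.

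Sphere and SP cells, both from the low-serum culture, were compared with each other. CSRP3 was higher in Sphere by 7.16 (SE 0.423, n = 4 against 4), the forkhead factor FOXS1 by 7.04, CD36 by 6.94, IGFL2 by 6.46 and MMP1 by 6.34, with CSRP3 and FOXS1 above background on 2 and 1 of 4 SP arrays. FOSB was lower by -7.92 (SE 0.817), HPD by -6.34, HAO2 by -6.31, STAC2 by -5.49 and APOC3 by -5.45. FAP was at least 412-fold higher in Sphere, CYTIP at least 155-fold and the chemokine CCL7 at least 96.8-fold, and PLXNC1, KRT6A and CXCL13 were at least 42.5-fold, 39.0-fold and 36.2-fold lower. In limma's test 12066 genes passed, 4631 higher and 7435 lower in Sphere, and 7520 differed by at least 2-fold. The median change of all genes was -0.19, and under quantile normalisation, where it was 0, the split was 5974 higher and 5643 lower. Run, medium, suspension, sorting and time cannot be told apart.

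Cell cycle genes were lower in Sphere than in SP (49 of 57 fell, 50 adjusted over the list alone; median -1.77, camera adjusted p 2.08e-07, adjusted p = 0.503 with an estimated correlation). MKI67 changed by -3.43 and the replication-licensing factor CDT1 by -2.97. Extracellular matrix genes were higher (23 of 45 rose, 23 adjusted over the list alone; median 0.80, camera adjusted p 6.27e-07, adjusted p = 0.083 with an estimated correlation). The matrix proteases MMP2 (1 of 4 SP arrays above background) and MMP7 rose by 6.16 and 4.45. Secreted hepatocyte proteins were lower (32 of 46 fell, 33 adjusted over the list alone; median -1.60, camera adjusted p 3.51e-05, adjusted p = 0.503 with an estimated correlation), and ALB and TF changed by -1.46 (SE 0.271) and -4.77. Glucocorticoid targets were lower (16 of 25 fell, 17 adjusted over the list alone; median -1.20, camera adjusted p 0.00108, adjusted p = 0.233 with an estimated correlation), with ZBTB16 at -4.50 and FKBP5 at -2.86. ATF4 and unfolded protein genes were higher (16 of 35 rose, 17 adjusted over the list alone; median 0.84, camera adjusted p 0.000194, adjusted p = 0.264 with an estimated correlation), with a median of 0.49 without SP array 2. DDIT4, SLC7A11 and TRIB3, stress-induced genes, rose by 5.20, 3.51 and 3.08. Oxidative phosphorylation genes were lower (39 of 77 fell, 42 adjusted over the list alone; median -0.57, camera adjusted p 0.000936, adjusted p = 0.718 with an estimated correlation), a call that ended without SP array 3 (0.114).

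Of the other lists, hypoxia, interferon, epithelial-mesenchymal transition, fibroblast, NF-kB and NRF2 genes were called higher in Sphere than in SP, and amino acid breakdown, drug-metabolising, bile acid and sterol synthesis genes lower, none of them with an estimated correlation (adjusted p from 0.119 to 0.718). Without SP array 2 the medians of the epithelial-mesenchymal, NF-kB and fibroblast lists were 0.31, 0.19 and 0.31 in place of 0.58, 0.36 and 0.61, and that of the interferon list was 0.42 in place of 0.63. The bile acid call ended without SP array 3 (0.184) or Sphere array 4 (0.0816), and the sterol synthesis call without SP array 3 (0.509, median -0.33) or Sphere array 1 (0.051), 3 (0.0668) or 4 (0.0531). POU5F1, CYP3A4 and HNF4A were lower by log2 changes of -2.41, -2.73 and -1.52, but HNF4A, above background on 1 of 4 Sphere arrays, changed by -0.30 and did not pass at a higher floor (0.0713). ABCG2 passed at -0.90 (adjusted p 0.0291) and lost its call without SP array 1 (0.0776) or 2 (0.0787), Sphere array 1 (0.1) or 4 (0.0504), and under quantile normalisation (-0.27, 0.504). AFP, KRT19, SOX9, NANOG and LDHA did not pass. With normexp SOX9 (-0.64, adjusted p 0.0112) and NANOG (-0.72, adjusted p 0.0117) did, and without SP array 2 so did LDHA (-0.82, adjusted p 0.00699) and SOX9 (0.0454). Median, mean and test differed in sign for the pluripotency, glycolysis, one-carbon, tricarboxylic acid cycle, endothelial and leukocyte lists.

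The Sphere effect at day 10 was set against the SP effect at day 4. The difference of both effects, Sphere against D10 minus SP against D4, had a median of -3.84 over the secreted hepatocyte proteins (41 of 46 lower, 41 adjusted over the list alone; camera adjusted p 9.74e-22, adjusted p = 0.0748 with an estimated correlation). It was -2.56 over drug-metabolising enzymes (33 of 53 lower, 34 adjusted over the list alone; camera adjusted p 1.68e-11, adjusted p = 0.0736 with an estimated correlation) and -2.37 over amino acid breakdown (31 of 40 lower, 32 adjusted over the list alone; camera adjusted p 8.09e-11, adjusted p = 0.0682 with an estimated correlation). Bile acid genes (-1.93; 16 of 26 lower, 17 adjusted over the list alone), extracellular matrix genes (1.59; 26 of 45 higher, 27 adjusted over the list alone) and epithelial-mesenchymal markers (1.24; 19 of 36 higher, 20 adjusted over the list alone) kept their calls with an estimated correlation (0.0466, 0.00472 and 0.00472). Of the other lists called, hypoxia, interferon, unfolded protein and fibroblast genes were higher and transcription factor, gluconeogenesis, oxidative phosphorylation, fatty acid oxidation and glucocorticoid genes lower, none of them with an estimated correlation (adjusted p from 0.0682 to 0.464). The difference equals Sphere against SP minus D10 against D4, so the change of the adherent cells between the days enters it. Against a common reference, the medians of secreted proteins agreed in sign in Sphere and SP (0.37 and 2.30 against D4, -2.03 and -0.28 against D10, the last not called). For this difference 8555 genes passed in limma, 3439 higher and 5116 lower, with a median change of -0.21 over all genes. Median, mean and test differed in sign for the pluripotency, glycolysis, one-carbon, cell cycle and endothelial lists.

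Embryonic stem cells differed from HepaRG in more genes than any HepaRG-derived groups differed from each other. Against D4, GSTP1, a glutathione transferase, rose by 12.45 (SE 0.382, n = 3 against 4), the neuropeptide GAL by 12.10, LEFTY1 by 10.58, SPINT2 by 10.27 and IFITM1 by 9.93. UCHL1, ESRG and L1TD1 were at least 8807-fold, 3900-fold and 3115-fold higher. NNMT, a methyltransferase of liver, fell by 13.31 (SE 0.292), followed by CES1 (-10.88), SAA1 (-10.79), EZHIP (-10.75) and the retinol carrier RBP4 (-10.45). ALB, SAA2 and the fibrinogen chain FGG were at least 12570-fold, 3562-fold and 2876-fold lower. Against D10, GSTP1 (12.05), FSCN1 (11.54), TUBB6 (10.45), VIM (9.84) and IFITM1 (9.73) rose, and NNMT (-13.62), SAA1 (-12.84), ORM2 (-12.62), ORM1 (-12.44) and RBP4 (-12.34) fell. There UCHL1, GAL and ESRG were at least 8803-fold, 4634-fold and 3780-fold higher, and ALB, SAA2 and TTR at least 54060-fold, 24200-fold and 18470-fold lower. In limma's test 15502 genes passed against D4 (6667 higher, 8835 lower; median of all genes -0.20) and 16101 against D10 (6917 higher, 9184 lower; median -0.24). NNMT and SAA1 were well above background on 1 of 3 hESC arrays and EZHIP on 2, GAL and LEFTY1 on 1 of 4 D4 arrays, and FSCN1 and TUBB6 on 1 of 3 D10 arrays. The sizes and order of these changes are thus not exact. Here scan run and medium cannot be told apart from the cell line.

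Pluripotency factors were higher in hESC (35 of 38 against D4 and 34 against D10; 36 and 34 adjusted over the list alone), with medians of 7.35 and 7.61, and both calls held with an estimated correlation (0.000162 and 0.000258). NANOG was at least 1766-fold higher than in D4, DPPA4 at least 992-fold, and POU5F1 rose by 8.59 (SE 0.385). Against D10, drug-metabolising enzymes (-5.12; 47 of 53 lower, 47 adjusted over the list alone), hepatocyte transcription factors (-2.50; 26 of 30 lower, 26 adjusted over the list alone), ABC transporters (-2.12; 14 of 22 lower, 14 adjusted over the list alone) and glucocorticoid targets (-3.03; 19 of 25 lower, 19 adjusted over the list alone) kept their calls with an estimated correlation (from 0.0274 to 0.0467). So did hepatoblast markers (0.85; 19 of 36 higher, 19 adjusted over the list alone; 0.0364) and endothelial markers (1.12; 8 of 13 higher, 8 adjusted over the list alone; 0.0467). Secreted hepatocyte proteins had medians of -4.94 and -7.89 against D4 and D10 (35 and 44 of 46 lower, 35 and 44 adjusted over the list alone; adjusted p = 0.227 and 0.0904 with an estimated correlation). Higher levels were also found for cell cycle genes (35 and 51 of 57, 35 and 53 adjusted over the list alone; medians 1.39 and 3.04), with adjusted p = 0.64 and 0.296 with an estimated correlation. Glycolysis genes were higher (16 and 17 of 27, 16 and 17 adjusted over the list alone; medians 1.14 and 1.19), with adjusted p = 0.121 and 0.103 with an estimated correlation, and the lactate dehydrogenase LDHB rose by 8.58 against D4. Oxidative phosphorylation genes were lower (39 and 57 of 77, 39 and 57 adjusted over the list alone; medians -0.60 and -0.94), with adjusted p = 0.716 and 0.535 with an estimated correlation.

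Of the anchor genes, MKI67 rose in hESC by 1.86 and 3.05 against D4 and D10, while CYP3A4, AFP and KRT19 fell in both comparisons, with AFP at -2.61 and -2.76. ABCG2 rose by 1.19 against D4, a call that ended without hESC array 2 (0.90, adjusted p 0.0502) or with normexp (0.22, adjusted p 0.405), and by 0.92 against D10 (adjusted p 0.0395), a call that ended without hESC array 2 (0.186) or 3 (0.171) or D10 array 1 (0.0612), 2 (0.07) or 3 (0.105), or with normexp (0.20, adjusted p 0.476), with 1.47 without hESC array 1. SOX9 passed at -0.98 against D10 (0.0377) and lost its call without any 1 of the hESC arrays or without D10 array 2 or 3 (adjusted p from 0.053 to 0.111), and under quantile normalisation (0.184). HNF4A was at least 3.78-fold lower than in D10. LDHA passed in neither comparison, but in both with array weights (0.1, 0.7 and 12.4 on hESC 1 to 3). The bile acid call against D4 (15 of 26 lower, 15 adjusted over the list alone; median -1.18, adjusted p = 0.393 with an estimated correlation) ended without D4 array 4 (0.0582). Endothelial markers against D4 (7 of 13 higher, 7 adjusted over the list alone; median 0.75, adjusted p = 0.086 with an estimated correlation) had a median of 1.31 without hESC array 1. Median, mean and test differed in sign for the sterol, hypoxia and immediate early lists in both comparisons, and against D10 also for the matrix, one-carbon and unfolded protein lists.

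Sphere cells and embryonic stem cells, which were scanned together and share serum replacement and bFGF, remained far apart; this comparison was chosen after the scan runs were seen. POU5F1 was higher in hESC by 9.40 (SE 0.385, n = 3 against 4) and NANOG by 9.71 (SE 0.557), and ALB was at least 20300-fold lower. GSTP1 rose by 12.25, the actin bundler FSCN1 by 11.48, GAL by 11.24, the motor KIF1A by 10.94 and the protease PRSS8 by 10.14. UCHL1, ESRG and L1TD1 were at least 10650-fold, 4806-fold and 3769-fold higher. The aldo-keto reductases AKR1B10 (-12.97) and AKR1B15 (-12.86), MMP7 (-12.53), NNMT (-12.20) and the chemokine CXCL1 (-11.60) fell. Of these, MMP7, NNMT and CXCL1 were well above background on 1 of 3 hESC arrays, both reductases on 2, and KIF1A and PRSS8 on 1 and 2 of 4 Sphere arrays. The decoy receptor IL13RA2 and VNN1 were at least 3300-fold and 3087-fold lower. In limma's test 13462 genes passed, 6620 higher and 6842 lower in hESC, and 10140 differed by at least 2-fold.

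Pluripotency factors had a median of 5.98 (35 of 38 higher, 35 adjusted over the list alone). On the 2 slides with both groups it was 5.92 and 6.38, against the slide as the cause. NF-kB genes (-3.75; 36 of 46 lower, 36 adjusted over the list alone), interferon genes (-2.69; 26 of 37 lower, 27 adjusted over the list alone), hepatocyte transcription factors (-2.14; 22 of 30 lower, 22 adjusted over the list alone) and ABC transporters (-1.13; 13 of 22 lower, 14 adjusted over the list alone) were lower in hESC, and these 5 calls held with an estimated correlation (0.000271 for pluripotency factors and 0.0208 for the others). Secreted hepatocyte proteins (-5.94; 40 of 46 lower, 40 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation) were lower and cell cycle genes higher (3.25; 52 of 57, 52 adjusted over the list alone; adjusted p = 0.266 with an estimated correlation). Oxidative phosphorylation genes were slightly higher in hESC (20 of 77 rose, 10 adjusted over the list alone; median 0.31, adjusted p = 0.707 with an estimated correlation), a call that ended without hESC array 2 (0.0921) or Sphere array 4 (0.0544) and under quantile normalisation (0.111). Sterol synthesis genes (12 of 35 rose, 12 adjusted over the list alone; median 0.53, adjusted p = 0.593 with an estimated correlation) lost their call without hESC array 2 (0.0559, median 0.33) and had a median of 0.96 without hESC array 1. Endothelial markers (7 of 13 rose, 9 adjusted over the list alone; median 0.89, adjusted p = 0.123 with an estimated correlation) lost theirs without hESC array 2 (0.0575) or Sphere array 2 (0.0584).

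Genes that differed by at least 2-fold were compared across pairs of comparisons that share no array, although D4 and D10, the reference groups, come from the same run. Sphere against D10 and SP against D4 shared 800 genes higher in both (453 for independent lists) and 806 lower in both (331), and 641 went opposite ways (875). Sphere against D10 and hESC against D4 shared 981 higher (574 for independent lists) and 2385 lower (1072), and 902 went opposite ways (1569). Sphere and hESC also come from 1 run, so a run difference enters both comparisons of that pair and its overlap. SP against D4 and hESC against D10 shared 834 higher (867 for independent lists) and 1000 lower (596), and 1307 went opposite ways (1601). In the pair chosen after the scan runs were seen, hESC against Sphere and D10 against D4, 129 were higher in both (180 for independent lists) and 249 lower in both (121), while 669 went opposite ways (309). The log2 changes correlated across genes at r = 0.21 in the first pair and -0.14 in the last, and genes are not independent replicates.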

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

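The tests below of ribosomal genes, scaling, runs, SP array 2, unsorted arrays, D10 array 1 and its slide were chosen after seeing the result. The brightness test and the splits of the samples were planned.

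The Sphere effect (against D10) lay below the SP effect (against D4) for hepatocyte genes, by a test of the difference itself. Only the bile acid call held with an estimated correlation (adjusted p = 0.0466). The secreted proteins then had an adjusted p of 0.0748, drug-metabolising enzymes 0.0736, and amino acid breakdown and transcription factors 0.0682 each. The median difference was -3.84 for secreted hepatocyte proteins (-2.03 in Sphere and 2.30 in SP; camera adjusted p 9.74e-22) and -2.56 for drug-metabolising enzymes (-1.66 and 1.21; 1.68e-11). It was -2.37 for amino acid breakdown (-1.45 and 0.96; 8.09e-11), -1.93 for bile acid genes (-1.60 and 1.05; 1.73e-07) and -1.08 for hepatocyte transcription factors (-0.63 and 0.60; 0.000111). The references differ in day, and D10 itself was above D4 in these lists, so the opposite signs depend on the references. Against D10 the medians of all 5 lists were negative in both groups (secreted proteins -2.03 in Sphere and -0.28 in SP), and against D4 they were positive in both (0.37 and 2.30) except for amino acid breakdown in Sphere (-0.15). None was called with an estimated correlation (adjusted p from 0.165 to 0.905).

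Single arrays lay far from the other 3 of their group in 23 of 590 groups of 4 tested (3.90%), where chance gives about 1 in 20. The number given is the gap to the nearest array over the range of the group. SP array 3 stood apart for SAA2 (0.861), SAA3P (0.9) and ACSM2B (0.852), which were high on it, for CDT1 (0.842), CGB3 (0.848), GPM6B (0.965) and S100A2 (0.875), which were low, and for PPBP (0.891), which was high. NR1I2 was high on SP array 4 (0.926), and the score of epithelial-mesenchymal markers was low on SP array 2 (0.94). Among D4 arrays, SOX9 (0.854) and CIDEC (0.853) were high on array 4, COL8A2 (0.921) and PLXNC1 (0.974) high on array 3, and ITGB3 low on array 2 (0.873). HMMR (0.891) and IGF2BP3 (0.903) were high on D4 array 1 and its sterol synthesis score was low (0.86). Among Sphere arrays, array 1 was low in the cell cycle score (0.869), the sterol synthesis score (0.832) and FKBP5 (0.928), array 2 high in the tricarboxylic acid cycle score (0.867), and array 4 high in CPS1 (0.863).

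The lower level of oxidative phosphorylation genes in Sphere than in D10 (median -1.28, interval over genes from -1.50 to -1.17; adjusted p = 0.233 with an estimated correlation) was weighed. Of 10000 random lists matched on brightness, 0% had a median as low (the middle 95% lay between -0.42 and -0.09), quantile normalisation left the median at -0.99, and the 84 ribosomal protein genes, also short and abundant, fell less (-0.52, interval from -0.58 to -0.43). These values argue against brightness, the scaling and a loss of short transcripts as the whole cause. Only in Sphere against SP did ribosomal genes (-0.42) lie within the list's interval (-0.69 to -0.35), so that loss stays open there. The scan run stays open, since run and group cannot be told apart. In hESC against Sphere, of 1 run, the list's median of 0.31 lay among those of matched lists (-0.19 to 0.35). That call ended without hESC array 2 or Sphere array 4 and had adjusted p = 0.707 with an estimated correlation. Medium and sphere culture stay open, untested.

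The higher immediate early genes in SP (median 0.40; adjusted p = 0.627 with an estimated correlation) were weighed next. Without SP array 2, the array with the lowest 75th percentile, the list was still called by camera's preset correlation (adjusted p 0.00385), against that array as the cause, while the call ended without SP array 3 (0.16). The highest score of the list on an unsorted array was 0.28 (hESC array 1), and every SP array lay above it. Sorting, scan run and a property of the population cannot be told apart, since only SP was sorted and it was scanned alone.

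The day 4 level of cell cycle genes on D10 array 1 (score 0.28, against -2.05 and -1.77 on the others) was weighed last. Its score for secreted hepatocyte proteins was 2.39, between those of the other D10 arrays (2.16 and 2.56) and above the highest D4 array (0.41), which argues against day 4 cells or RNA under its label. D10 array 3, on the same slide, had a cell cycle score of -1.77, against the slide as the cause. A difference between the cultures stays open and was not tested.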

How the results depend on the processing

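The hESC vs Sphere comparison with its alternatives, the highest floor, array weights, leaving out SP 2 and hESC 1 together, and the block by the numbers of the authors' table were chosen after seeing the data. No named gene that passed reversed. Over up to 16 settings, leaving single arrays out aside, the number of passing genes ran from 7981 to 15640 in Sphere vs D10, 7832 to 14771 in Sphere vs D4, 6632 to 12989 in SP vs D4, 6902 to 14259 in SP vs D10, 8435 to 15694 in Sphere vs SP, 873 to 5256 in D10 vs D4, 10824 to 19634 in hESC vs D4, 11191 to 20620 in hESC vs D10, 8909 to 18744 in hESC vs Sphere and 5885 to 12673 for the Sphere effect minus the SP effect. Counts beyond 1.5 times the reported ones came from the fewer genes tested when probes had to be well above background on all 18 arrays (SP vs D4 6632 in place of 10087, D10 vs D4 1286 in place of 2033, hESC vs Sphere 8909 in place of 13462), from array weights (Sphere vs D10 15640 in place of 10342, D10 vs D4 5256 in place of 2033) and, for D10 vs D4, from the slide as a fixed block (873) and from leaving out SP 2 and hESC 1 (3609), where the cause was not tested. Without 1 array, D10 vs D4 passed between 1135 genes (without D10 array 2; 1291 without D10 array 3) and 1883 (without D4 array 4). Without a minimum fold, more genes were counted and the overlaps in the same direction rose to 3305, 5745, 3762 and 580 from 1606, 3366, 1834 and 378.

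Of 156 list calls, 26 held with an estimated correlation, which allows for genes of a list varying together, and fry gave 195 calls. Quantile normalisation ended 4 of 14 calls in SP vs D10, 2 of 11 in SP vs D4 and 1 each in Sphere vs D10, D10 vs D4 and hESC vs Sphere, each named in the report. It added those of immediate early genes in Sphere vs D10 (0.036) and Sphere vs SP (0.0431), fatty acid oxidation in SP vs D4 (0.0207) and, for the difference of effects, the tricarboxylic acid cycle (0.0422), sterol synthesis (0.0145) and NRF2 genes (0.0489). Named genes had 8707 values under alternatives, of which 8482 kept the call, 104 lost it, 72 gained it and 49 changed sign without having passed. For 221 values of named genes the filter on all 18 arrays left no probe, and a slide as a fixed block could be fitted only for D10 vs D4 and hESC vs Sphere. The random block for slides had a correlation of -0.21.

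Except between SP and D10, where all 3 same-numbered pairs had correlated deviations over 0.1, the replicate numbers do not pair the samples: 5 of 33 pairs lay over 0.1, with a median of -0.02, and 4 arrays correlated best with their own number. With the replicate number as a block, 9202 genes passed in Sphere vs D10, 9564 in Sphere vs D4, 9531 in SP vs D4, 8806 in SP vs D10, 11557 in Sphere vs SP, 1609 in D10 vs D4, 15146 in hESC vs D4, 15759 in hESC vs D10, 12861 in hESC vs Sphere and 7298 for the difference of effects, and 156 lists were called. The block added the calls of secreted hepatocyte proteins in SP vs D10 (0.048) and of ABC transporters in D10 vs D4 (0.0399), and ended those of NRF2 genes in Sphere vs D10 (0.0516) and of hypoxia genes in D10 vs D4 (0.058).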

Other observations

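The tests of insulin and hydrocortisone below were chosen only after the result was seen; the splits of the samples were planned.

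IGFBP1, which liver cells make when insulin is low, was among the largest rises in Sphere and SP against D10 (6.62 and 6.46). Both had less insulin than D10 in the adherent phase (1 against 5 µg/ml), but that in suspension is not stated. If low insulin were the cause, other genes that insulin represses may be expected to rise in both comparisons, and 0 of the 3 tested did; PCK1 was not among the genes tested. PPARGC1A fell in both (-2.50 and -0.92), G6PC1 was at least 9.85-fold lower in Sphere and lower in SP (-1.54), and IRS2 did not pass in either (0.22 and 0.37). Against D4, G6PC1 was higher in SP (at least 2.81-fold, with 3 of 4 SP arrays above background) and IRS2 again passed in neither. These genes were chosen outside the naming rule. Hydrocortisone and run differ too, so low insulin stays open.

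Glucocorticoid targets were lower in Sphere than in D10 (median -1.74; adjusted p = 0.0852 with an estimated correlation), and a candidate explanation is less hydrocortisone, which is stated as 50 µM for D10 and 1 µM for the adherent phase of both SP and Sphere. SP cells had a median of -0.38 against D10, a call that ended without SP array 2 (0.0754) and under quantile normalisation (0.142). Sphere cells lay below SP cells (-1.20). With an estimated correlation these had adjusted p = 0.441 and 0.233. Since the hydrocortisone in suspension is not stated and each group has its own run, medium, suspension and run cannot be told apart.

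Markers of other cell types gave no common pattern. Fibroblast markers were lower in SP than in D4 (median -0.40; adjusted p = 0.237 with an estimated correlation) and higher in Sphere than in SP (0.61; adjusted p = 0.166 with an estimated correlation), where FAP was at least 412-fold higher. Without SP array 2 these medians were -0.24 and 0.31, and the first was -0.24 without D4 array 3; its call ended without SP array 3 (0.0589) or D4 array 4 (0.0613). They were also lower on day 10 than on day 4 (-0.25; adjusted p = 0.144 with an estimated correlation), a call that ended without D4 array 2 (0.0528, median -0.08) or D4 array 4 (0.0851). In the main fit camera called leukocyte markers in none of the 9 comparisons and endothelial markers only in those with hESC. By fry leukocyte markers were lower in hESC in all 3, and camera called them against Sphere with the slide as a block (0.0441), against D4 without D4 array 2 or 4 and against D10 without D10 array 3 (0.0467).

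Other splits of the same arrays into groups of the same sizes were counted, with genes passing in a fit of those arrays alone. For 8 comparisons only the real split of 35 had so many genes, the least share possible. The real and the highest other counts were 14278 and 5 in Sphere vs D10, 12035 and 2 in Sphere vs D4, 8013 and 0 in SP vs D4, 11778 and 1 in Sphere vs SP, 2655 and 2 in D10 vs D4, and 13569 and 2 in hESC vs Sphere. In SP vs D10 they were 8400 and 4917, the latter with SP array 3 beside the D10 arrays, and in hESC vs D4 13917 and 1418, the latter with D4 array 4 beside the hESC arrays, which points to structure among the samples. The difference of effects had 9658 genes with real labels and at most 21 in other label sets of 100, which mix groups and cannot test it. In hESC vs D10 there are only 10 splits, too few for a share under 0.05, with 15571 genes in the real one and 0 at most in the others.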
